A study of Mus musculus with 24 samples.

How the data were processed

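Total RNA was extracted from sorted alpha and beta cells with a column kit for small samples, and stranded libraries were made after ribosomal RNA removal, per the labels' protocols. The submitters' processing notes name the aligner STAR, the package edgeR and the build mm10, with no versions. The gene annotation, the strand setting of the counting and the filter that left 14027 genes are not given in the sources used here.

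The authors deposited log2 values, which the values themselves show to be log2 RPKM (reads per kilobase of gene, scaled to library size). In each library they fall on whole steps above the value of a gene without reads, with a prior count whose mean over libraries is 2.0 and library sizes that hold a scaling factor between libraries. From these steps whole reads were recovered for all 14027 genes in the 24 libraries (largest deviation from a whole number 8.4e-08). The recovered reads gave a median of 206 reads per gene and 0.77% of values at 0. A log2 difference understates the change of genes with few reads because of the prior count.

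The labels do not say whether the 2 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Replicates differed by more than sampling noise in every group (chi-square per gene 2.47 to 44.8), and all 24 were used.

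Gene identifiers were matched to the GENCODE annotation of GRCm38, the assembly that mm10 names. Of the 14027 identifiers 13802 matched, and 12399 had the same symbol; current symbols are printed for list members whose symbol changed (Ciart, Msmo1, Ffar4). In the table, 144 entries shared a symbol with another. Chromosome positions are those of the annotation, counted from 1. The erythroid and mitochondrially encoded lists, and some members of other lists, were not analysed here.

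The planned tests assumed read counts, with limma on log2(value + 1) if the values were normalized. The values were already log2 with a prior count, so the tests used them as deposited, and log2(RPKM + 1) and log2(RPKM + 0.1) were run as alternatives. All tests were made with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and robust estimation, and p-values were adjusted by the Benjamini-Hochberg method over all 14027 genes. No further filter was applied. The cell types were compared with the time point as a factor of 6 levels, and genes were called at an adjusted p under 0.05 and a fold of at least 2. Rhythms were fitted as a 24 h cosine in each cell type in one model over all 24 libraries and called by the F-test of the 2 cosine terms in that cell type. The difference of rhythm was tested as the F-test of the differences of these terms. Peak times carry the standard error of the fit. Means of RPKM were computed from the recovered reads without a prior count, and their SD over 12 libraries includes the time of day.

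The peak time of core clock genes was compared by the median over genes of the difference between alpha and beta cells, in hours, among genes called rhythmic in both. Its exact permutation test centred the values on each cell type's mean and reassigned cell types within time points. Gene lists were tested between cell types with camera at a correlation between genes of 0.01 and again with an estimated correlation, and among rhythmic genes with a one-sided Fisher test, in which genes are not independent replicates. The 26 lists, the comparisons, the alternatives and the naming rule were fixed before the data were examined. Of the lists, 24 had at least 3 measured genes. Some genes belong to several lists, so the counts of different lists are not separate evidence.

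The rule for named genes took the 8 largest folds in each direction among called genes with at least 10 CPM in the higher cell type and one direction at all 6 time points, and up to 4 examples per list. For rhythms it took the 10 rhythmic genes with the lowest p in each cell type, all core clock genes, up to 3 rhythmic examples of every other list, and the 10 lowest p of the difference of rhythm. Predicted genes were counted but not named, and Ins1, Ins2, Gcg, Sst and Ppy were always named. Some genes that the rule takes are not reported here. Peg3 and the list members below the thresholds were named after their values were seen.

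The scripts were tested on simulated reads of the 14027 genes, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. At an adjusted p under 0.05, without the fold threshold, the comparison of cell types recovered 98.5%, 100% and 100%, with 8 false calls. With these folds as the range between peak and trough, the rhythm test recovered 55.2%, 95.5% and 100% in alpha cells and 62.7%, 95.5% and 100% in beta cells, with 7 false calls in each. The test of the difference of rhythm recovered 11.9%, 68.7% and 98.5%, with 4 false calls. The changed genes were drawn from those above a minimum mean number of reads. Reads were simulated independently for each gene, without library effects shared between genes. The false calls thus do not measure the error of the real libraries, which may share such effects. Alternatives covered the normalization, the pseudocount, precision weights (limma-voom on the recovered reads), the form of the rhythm, covariates, a block for the replicate number and leaving out each library in turn.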

Results

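RNA was measured in 2 endocrine cell types of the mouse pancreatic islet, alpha cells, which secrete glucagon, and beta cells, which secrete insulin. The cells came from a triple reporter mouse strain, and the islets were isolated at 6 zeitgeber times (ZT, hours of the lighting cycle): ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20. Each combination of cell type and time had 2 libraries, which gave 12 alpha and 12 beta libraries. The deposited table held 14027 genes. The reads behind it ranged from 4944982 in replicate 2 of the ZT12 alpha cells to 12364190 in replicate 2 of the ZT8 alpha cells. The series title names distinct properties of the clocks of the 2 cell types, and the design allows a comparison of the cell types, a search for daily rhythms in each, and a test of whether the rhythms differ.

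The hormone genes differed between the cell types in the direction of the labels. Gcg, which encodes glucagon, had 125000 ± 24000 RPKM in alpha cells and 287 ± 519 RPKM in beta cells (mean ± SD, n = 12 libraries each). The beta mean of Gcg rests on replicate 1 of ZT4, with 1.52% of the mean alpha level against at most 0.297% in the other beta libraries, and was 139 ± 101 RPKM without it. Ins2 and Ins1, the insulin genes, had 174000 ± 38500 and 81600 ± 17900 RPKM in beta cells against 1170 ± 954 and 515 ± 405 RPKM in alpha cells. Between 16% and 24.2% of the reads of an alpha library came from Gcg, and between 16.4% and 26.0% of the reads of a beta library came from Ins1 and Ins2 together. Ins1 and Ins2 are near-identical in sequence, so the split of reads between them is uncertain. The share of insulin reads in alpha cells was highest in replicate 1 of ZT4 (0.506% of reads) and replicate 1 of ZT16 (0.356%), and the share of Gcg reads in beta cells was highest in replicate 1 of ZT4 (0.281%).

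Folds here are differences of mean log2 values, which weigh single high libraries less than a ratio of mean RPKM. After Gcg (865-fold), the genes with the largest fold in alpha cells included Pdk4, a kinase that inhibits pyruvate dehydrogenase (371-fold), the transcription factor gene Irx1 (370-fold), the glycosyltransferase gene Galnt13 (288-fold), the vasopressin receptor gene Avpr1b (220-fold), Higd1a (186-fold) and the endothelin gene Edn3 (183-fold). The largest folds in beta cells were those of Ins1 (193-fold) and Ins2 (183-fold), the peptide hormone gene Ucn3 (145-fold), Sytl4, which encodes granuphilin of the secretory granule (145-fold), the glucose transporter gene Slc2a2 (140-fold), Fam151a (128-fold), Tmem215 (123-fold) and Prss53 (113-fold). Each of these genes had a limma adjusted p of at most 1.5e-14, went the same way at all 6 time points and had no overlap between the 12 alpha and 12 beta libraries. For Gcg the log2 difference was 9.76 (SE 0.411, limma adjusted p = 7.1e-15). In the mm10 assembly Irx1 lies on chromosome 13 from 71957921 to 71963723, Ucn3 on chromosome 13 from 3940688 to 3945349 and Slc2a2 on chromosome 3 from 28697903 to 28731359, all annotated as protein-coding genes.

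**Figure D1:**
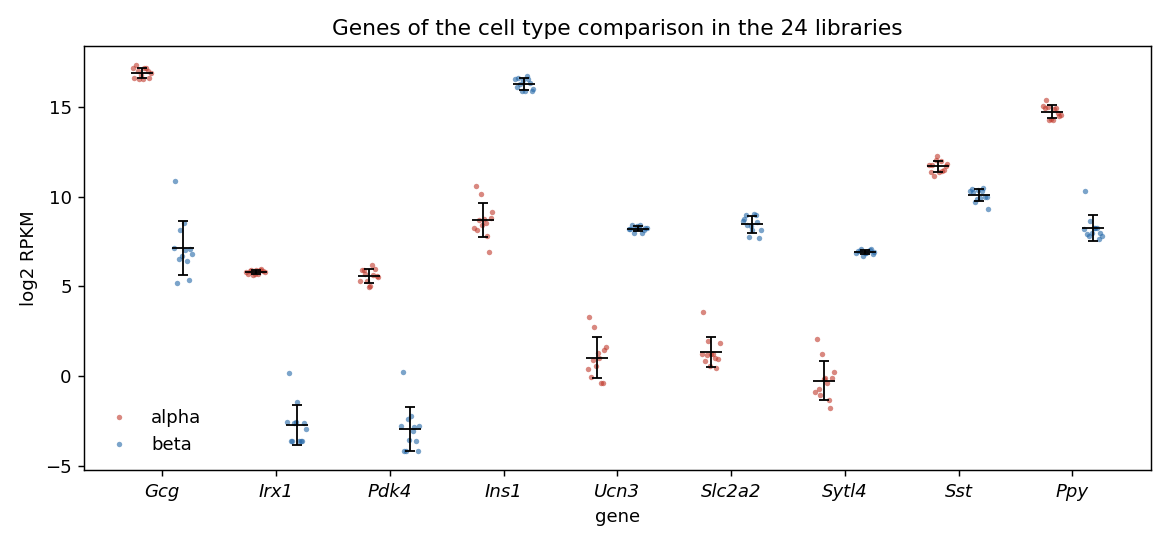
Expression (log2 RPKM, vertical axis) of 9 genes in each of the 12 alpha (red) and 12 beta (blue) libraries, with the mean as a bar and the SD as the error bar. Gcg, Irx1 and Pdk4 lie far higher in alpha cells and Ins1, Ucn3, Slc2a2 and Sytl4 in beta cells, while Sst is 3.05-fold and Ppy 89.1-fold higher in alpha cells.

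Of the 14027 genes, 2903 (20.7%) differed between the cell types at an adjusted p under 0.05 and a fold of at least 2 (limma, Benjamini-Hochberg). Of these, 1565 were higher in alpha cells and 1338 in beta cells, and 2889 kept their direction at all 6 time points. In 2262 of them the 12 alpha and 12 beta libraries did not overlap, which chance gives for a gene with a probability of 7.4e-07 if all 24 libraries are independent. The labels do not show that they are. The 2262 were also counted among genes called from the same values, so they are no separate evidence. With log2(RPKM + 1) in place of the deposited values 1602 genes passed, 690 higher in alpha and 912 in beta cells, which moved the share higher in alpha from 53.9% to 43.1%. A filter at a mean log2 RPKM above 0, chosen after seeing the data, gave 1755 genes, 739 higher in alpha and 1016 in beta cells (42.1% higher in alpha).

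Of 24 gene lists fixed in advance, 9 differed between the cell types by camera, and 1 of them, alpha cell identity, with an estimated correlation between genes. Of 12 measured alpha cell identity genes, 11 were higher in alpha cells (11 adjusted over the list alone), with Irx2 at 146-fold beside Gcg and Irx1. Peg3 at 1.23-fold was below the threshold. The list as a whole was higher in alpha cells (camera, adjusted p = 1.4e-08, and adjusted p = 0.016 with an estimated correlation). Of 18 beta cell identity genes, 17 were higher in beta cells (17 adjusted over the list alone). The exception was the zinc transporter gene Slc30a8 at 1.45-fold (camera, adjusted p = 1.7e-11, and adjusted p = 0.21 with an estimated correlation). The transcription factor genes Pdx1 and Mafa were 24.1-fold and 112-fold higher in beta cells. Of 14 pan-endocrine genes, 1 was higher in alpha and 4 in beta cells (5 adjusted over the list alone, camera adjusted p = 0.1, and adjusted p = 0.26 with an estimated correlation). Among them were the granin gene Scg2 (6.39-fold, beta), Insm1 (3.99-fold, beta), Scg3 (2.42-fold, beta) and Pcsk1n (2.18-fold, alpha).

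Genes of protein folding and of sterol synthesis were called in beta cells, with 0 in alpha cells. Of 24 genes of the unfolded protein response, 14 were higher in beta and 0 in alpha cells (14 adjusted over the list alone). Ero1lb, an oxidase of disulfide bond formation in the endoplasmic reticulum, had 963 ± 118 RPKM in beta and 39.6 ± 7.8 in alpha cells. Ero1lb is also counted in the beta cell identity list. Trib3, Edem1 and Sdf2l1 were 12.1-fold, 5.68-fold and 5.5-fold higher in beta cells (camera, adjusted p = 2.2e-09, and adjusted p = 0.21 with an estimated correlation). Of 18 genes of cholesterol synthesis, 8 were higher in beta and 0 in alpha cells (8 adjusted over the list alone). Msmo1 was 5.15-fold, Insig1 4.74-fold and Sqle 3.77-fold higher (camera, adjusted p = 1.7e-06, and adjusted p = 0.21 with an estimated correlation). Among 14 genes of prohormone processing and granules, 4 were higher in beta and 1 in alpha cells (5 adjusted over the list alone, camera adjusted p = 0.28, and adjusted p = 0.7 with an estimated correlation). The prohormone convertase gene Pcsk1 (67.9-fold, beta), also counted in the beta cell identity list, led them. The list shares other genes, among them Scg2, Scg3 and Pcsk1n, with the pan-endocrine list. Among 47 genes of oxidative phosphorylation only Cox5a passed (2.8-fold higher in beta cells, 1 adjusted over the list alone, 34 at an unadjusted p under 0.05 without the fold threshold). The list had a median log2 difference of -0.35 (camera, adjusted p = 0.00061, and adjusted p = 0.7 with an estimated correlation).

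Of 20 measured receptors of secretion, 6 were higher in alpha and 12 in beta cells (18 adjusted over the list alone, camera adjusted p = 0.032, and adjusted p = 0.26 with an estimated correlation). The somatostatin receptor gene Sstr2 was 93.5-fold higher in alpha cells, and the prolactin receptor gene Prlr (104-fold) and the GLP-1 receptor gene Glp1r (92.2-fold) were higher in beta cells. Of 20 genes of glucose sensing and excitability, 4 were higher in alpha and 5 in beta cells (9 adjusted over the list alone, camera adjusted p = 0.3, and adjusted p = 0.7 with an estimated correlation). Hexokinase 1, the low-Km glucose kinase encoded by Hk1, was 117-fold higher in alpha cells at 4.94 ± 0.693 RPKM. Trpm5 and G6pc2 were 106-fold and 85.1-fold higher in beta cells. Both are also counted in the beta cell identity list, as are Prlr and Glp1r. Of 21 genes of exocytosis, 1 was higher in alpha cells (Stx1a, 2.92-fold) and 5 in beta cells (6 adjusted over the list alone, camera adjusted p = 0.18, and adjusted p = 0.49 with an estimated correlation). The latter included Doc2b (4.73-fold, 0.859 RPKM in beta and 0.152 RPKM in alpha cells) and Syt13 (2.42-fold). Of 14 amino acid transporter genes, 5 were higher in alpha cells, led by Slc38a5 (27-fold), Slc7a7 (8.85-fold) and Slc7a2 (3.39-fold). Another 2 were higher in beta cells, among them Slc1a4 (2.62-fold, 7 adjusted over the list alone, camera adjusted p = 0.62, and adjusted p = 0.8 with an estimated correlation). The median log2 difference of that list was -0.05, while its mean was 0.58. Slc38a5 and Slc7a2 are also counted in the alpha cell identity list.

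Of 18 immediate early genes, 10 were higher in alpha and 0 in beta cells (10 adjusted over the list alone, camera adjusted p = 0.014, and adjusted p = 0.7 with an estimated correlation). Atf3 was 20.7-fold, Klf4 12.8-fold, Egr2 6.69-fold and Zfp36 4.64-fold higher. These genes varied between the libraries of one time point, and Atf3 had 43.4 ± 81.2 RPKM in alpha cells (SD, n = 12), and 20.2 ± 10.5 RPKM without replicate 2 of ZT8. Egr2 had 2.01 ± 4.4 RPKM in alpha cells, and 0.749 ± 0.531 RPKM without that library, against 0.0932 ± 0.118 RPKM in beta cells. Of 9 measured glucocorticoid and fasting targets, 2 were higher in alpha cells (Pdk4 and the transcription factor gene Zbtb16, 29.8-fold) and 3 in beta cells (Mt1, 3.37-fold, Sgk1, 2.95-fold, and Mt2, 2.39-fold), with 5 adjusted over the list alone (camera, adjusted p = 0.85, and adjusted p = 0.87 with an estimated correlation). The median log2 difference of that list was -0.60 and its mean 0.89. Of 11 heat shock and cold-inducible genes, with a median of -0.05 and a mean of 0.10, 1 was higher in alpha cells (Hspb1, 2.42-fold, 1 adjusted over the list alone, camera adjusted p = 0.88, and adjusted p = 0.95 with an estimated correlation). Of 14 cell cycle genes 1 was higher in beta cells (Rrm2, 3.89-fold, 1 adjusted over the list alone, camera adjusted p = 0.55, and adjusted p = 0.8 with an estimated correlation).

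All 6 delta cell markers were higher in alpha cells (6 adjusted over the list alone, camera adjusted p = 0.0041, and adjusted p = 0.26 with an estimated correlation). Rbp4 was 16.6-fold, Ptprz1 3.76-fold, Sst 3.05-fold and Hhex 3.05-fold higher. All 3 PP cell markers, Ppy (89.1-fold), Sertm1 (84.5-fold) and Pyy (56.1-fold), were higher in alpha cells (3 adjusted over the list alone, camera adjusted p = 0.0034, and adjusted p = 0.21 with an estimated correlation). Ppy held 1.1% to 2.08% of the reads there. Of 6 stromal markers 4 were higher in alpha cells (4 adjusted over the list alone, camera adjusted p = 0.076, and adjusted p = 0.49 with an estimated correlation). They were Col1a2 (44.3-fold, 4.41 ± 0.752 RPKM), Col1a1 (2.15-fold), Rgs5 (2.1-fold) and Pdgfrb (2-fold), the last 3 all below 1 RPKM. Pdgfrb lies on the fold threshold and lost its call in 18 of 36 other settings, Col1a1 in 6 and Rgs5 in 5. Of 3 measured duct markers, Spp1 (5.12-fold) and Muc1 (2.4-fold, 0.4 against 0.122 RPKM) were higher in alpha cells (2 adjusted over the list alone). So were 2 of 3 measured glial markers, among them Cdh19 (5.91-fold, 0.471 against 0.0198 RPKM, 2 adjusted over the list alone). The camera test of the duct and glial lists gave adjusted p = 0.62 and adjusted p = 0.32 (adjusted p = 0.7 and adjusted p = 0.49 with an estimated correlation). Of 22 acinar markers only Bhlha15 was called (3.89-fold higher in beta cells, 1 adjusted over the list alone, camera adjusted p = 0.93, and adjusted p = 0.98 with an estimated correlation). Of the others, 0 of 5 endothelial and 0 of 8 immune markers were called by limma (0 adjusted over either list alone, 2 endothelial and 4 immune markers at an unadjusted p under 0.05). Those last lists had a camera adjusted p = 0.4 and adjusted p = 0.72, and adjusted p = 0.7 and adjusted p = 0.87 with an estimated correlation.

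Core clock genes were rhythmic in both cell types. Nr1d1, which encodes the repressor REV-ERB alpha, swung 8-fold between trough and peak in alpha cells and 7.77-fold in beta cells. It went from 0.966 RPKM at ZT20 to 7.12 RPKM at ZT8 in alpha cells and from 1.33 to 11.3 RPKM at the same times in beta cells (means of 2 libraries). Arntl, which encodes the activator BMAL1, peaked at ZT 1.0 ± 0.5 h in alpha cells and ZT 23.2 ± 0.3 h in beta cells (± SE) and folds of 7.39 and 22.4. Of 20 core clock genes, 16 were rhythmic in alpha cells and 18 in beta cells, all 16 in both, and 19 in each when adjusted over the list alone (limma F-test of a 24 h cosine). Core clock genes were called more often than other genes in both cell types (one-sided Fisher test, adjusted p = 8.5e-12 in alpha and 1.4e-11 in beta cells). Clock and Bhlhe40 were called in beta cells (limma, adjusted p = 0.0057 and 0.011) and had an adjusted p of 0.066 and 0.086 in alpha cells, and Rora and Rorb were called in neither. The limma test of the difference gave an adjusted p of 1 for Clock and for Bhlhe40. The alpha call of Per1 was lost in 10 of 40 other settings.

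In alpha cells Npas2 (ZT 2.6 ± 0.4 h) and Nfil3 (ZT 1.2 ± 0.8 h) peaked close to Arntl, followed by Nr1d1 (9.6 ± 0.2), Dbp (11.0 ± 0.4), Nr1d2 (11.2 ± 0.3), Bhlhe41 (12.1 ± 0.6) and Ciart (12.7 ± 0.7). Later came Tef (13.2 ± 0.3), Hlf (13.9 ± 0.8), Cry2 (14.3 ± 0.7), Per3 (14.8 ± 0.5), Per1 (17.0 ± 0.9), Per2 (17.6 ± 0.4) and Cry1 (21.7 ± 0.3). In beta cells the same genes peaked at ZT 1.1 ± 0.3 h for Npas2, 22.9 ± 0.4 for Nfil3, 8.0 ± 0.2 for Nr1d1, 9.8 ± 0.3 for Dbp, 9.9 ± 0.3 for Nr1d2, 11.6 ± 0.6 for Bhlhe41 and 11.1 ± 0.6 for Ciart. The others peaked at 11.6 ± 0.3 for Tef, 13.3 ± 0.5 for Hlf, 14.3 ± 0.6 for Cry2, 12.6 ± 0.5 for Per3, 15.1 ± 0.9 for Per1, 16.4 ± 0.4 for Per2 and 19.9 ± 0.3 for Cry1. In mean level, 4 of the 20 were called between the cell types (4 adjusted over the list alone, camera adjusted p = 0.55, and adjusted p = 0.7 with an estimated correlation). Rorb (3.71-fold) and Hlf (2.25-fold) were higher in alpha cells and Bhlhe40 (3.61-fold) and Ciart (2.25-fold) in beta cells. The fold of Rorb rests on few reads, with 0.132 ± 0.0475 RPKM in alpha and 0.0217 ± 0.0116 RPKM in beta cells.

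**Figure D2:**
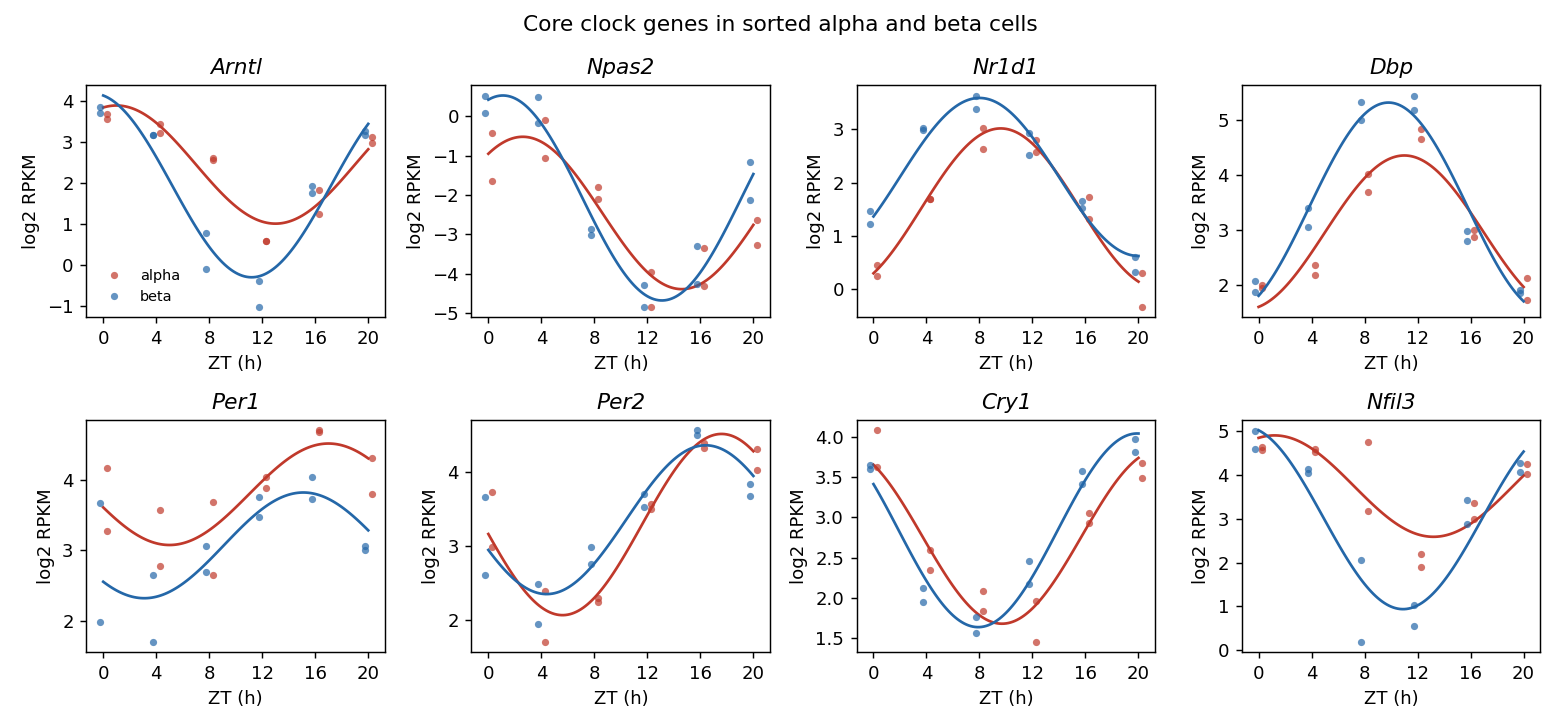
Expression (log2 RPKM, vertical axes) of 8 core clock genes against the time of islet isolation (ZT in h, horizontal axes), with 1 point per library, alpha cells in red and beta cells in blue, and the fitted 24 h cosine as a line. The alpha curve lies to the right of the beta curve, by 1.79 h for Arntl and 1.67 h for Nr1d1.

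Core clock genes peaked later in alpha than in beta cells. Among the 16 genes rhythmic in both, 15 peaked later in alpha cells, by a median of 1.51 h (mean 1.35 h, SD over genes 0.66 h). The shift was 2.29 h for Nfil3, 2.21 h for Per3, 1.97 h for Per1, 1.82 h for Cry1 and 1.79 h for Arntl, and it was smallest for Bhlhe41 (0.46 h) and Cry2 (-0.06 h). An exact two-sided permutation test, which reassigned the cell type labels within time points in all 46656 ways, gave p = 4.3e-05, the smallest it can give. The middle 95% of the reassigned medians lay between -0.81 and 0.81 h. For single genes the limma test of the difference of rhythm called 0 of the 20 core clock genes over all genes tested, 10 adjusted over the list alone and 10 at an unadjusted p under 0.05.

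**Figure D3:**
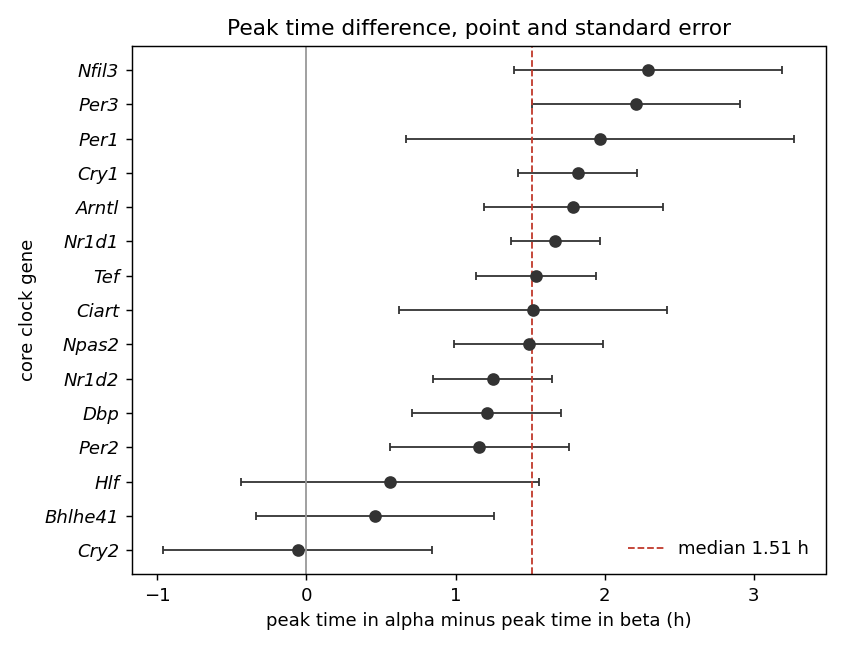
Peak time in alpha cells minus peak time in beta cells (h, horizontal axis) for 15 of the 16 core clock genes rhythmic in both cell types, with the standard error of the difference as the bar and the median of 1.51 h over all 16 as the dashed line. Only the point of Cry2 lies to the left of 0.

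The named genes with the lowest p of a rhythm in alpha cells included Nr1d1, Nr1d2, Tef, Cry1, Camta1, Dbp, Per2, Lpl and Mt2. Lpl, which encodes lipoprotein lipase, peaked at ZT 4.0 ± 0.4 h in alpha cells with a 3.88-fold range (limma, adjusted p = 4.4e-06) and at ZT 2.1 ± 0.4 h in beta cells with a 3.11-fold range. The transcription factor gene Camta1 peaked at ZT 15.0 ± 0.4 h in alpha cells (2.16-fold). In beta cells they included Nr1d1, Nr1d2, Dbp, Tef, Cry1, Spon2, Arntl, Npas2 and Fam84a. The extracellular matrix gene Spon2 peaked there at ZT 6.0 ± 0.3 h (4.23-fold, limma adjusted p = 1.0e-07), and Fam84a at ZT 0.3 ± 0.4 h (6.73-fold, adjusted p = 6.4e-06).

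In all, 1355 genes (9.66%) were rhythmic in alpha cells and 2241 (16%) in beta cells at an adjusted p under 0.05 (limma, Benjamini-Hochberg), with a median range between peak and trough of 1.71-fold and 1.65-fold. The lists shared 582 genes, against 216 for independent lists, and 92.4% of the shared genes peaked within 3 h of each other, with a median difference of 0.45 h. Deviations of same-numbered alpha and beta libraries correlated, from 0.041 at ZT20 to 0.647 at ZT0, so the 2 lists are not independent. The excess over 216 thus does not by itself measure rhythms common to both cell types. Peaks gathered in the windows ZT4 to ZT10 (704 genes in alpha, 859 in beta cells) and ZT16 to ZT22 (493 and 972 genes), which cover 50% of the day and held 88.3% and 81.7% of the calls. In the same libraries a 24 h cosine was fitted to the log2 ratio of the nuclear RNAs Malat1, Neat1 and Meg3 to ribosomal protein mRNAs. It had a peak at ZT 19.1 in alpha and ZT 18.4 in beta cells and a range of 2.36 and 2.38, without a test of this rhythm. Between libraries of one time point lay 34.4% and 44.2% of the variance of the ratio. With this ratio as a covariate, chosen after seeing the data, 143 genes were called in alpha and 802 in beta cells. In the fit without this covariate, the alpha count of 1355 became 348 without replicate 1 and 757 without replicate 2 of the ZT8 alpha cells. The alpha count there was 879 and 822 without those of ZT12. It was 676 and 619 without those of ZT16, 726 without replicate 1 of ZT20 and 2252 without replicate 1 of ZT4. The beta count of 2241, also without the covariate, became 1330 without replicate 1 of the ZT8 beta cells and 1269 without replicate 2 of ZT4. It was 1120 and 1077 without replicates 1 and 2 of ZT16.

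**Figure D4:**
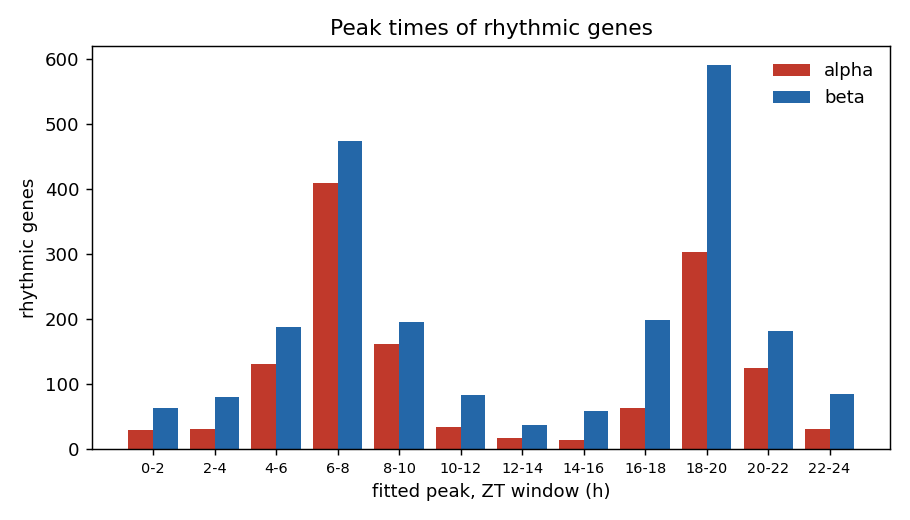
Number of rhythmic genes (vertical axis) by fitted peak time in windows of 2 h (horizontal axis) for alpha cells (red) and beta cells (blue). The tallest bars are those from ZT6 to ZT8, with 410 alpha and 475 beta genes, and from ZT18 to ZT20, with 304 and 591.

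Of 24 genes of the unfolded protein response, 13 were rhythmic in beta cells (16 adjusted over the list alone), more often than other genes (one-sided Fisher test, adjusted p = 0.0003), and 4 in alpha cells (6 adjusted over the list alone, adjusted p = 0.89). Their peaks lay between ZT16 and ZT22 in 8 of the 13 in beta cells and 3 of the 4 in alpha cells. Sdf2l1, Pdia6 and Creld2 peaked in beta cells at ZT 22.9 ± 0.5, 22.5 ± 0.5 and 21.3 ± 0.6 h with ranges of 2.41-fold, 2.03-fold and 2.34-fold. In alpha cells Edem1 (ZT 19.9 ± 0.8 h), Herpud1 (ZT 12.4 ± 1.0 h) and Sdf2l1 (ZT 22 ± 1.0 h) were called, and the calls of Herpud1 and Sdf2l1 were lost in 10 and 14 of 40 other settings. The limma test of the difference of rhythm called 0 of the 24 (0 adjusted over the list alone, 6 at an unadjusted p under 0.05). Of 18 genes of cholesterol synthesis, 6 were rhythmic in alpha and 7 in beta cells (8 and 10 adjusted over the list alone, Fisher adjusted p = 0.065 and 0.16). The list passed the Fisher test in alpha cells in 14 of 33 other settings and in beta cells in 2. Sqle peaked at ZT 23.8 ± 0.8 h in alpha cells, and Lss and Fdps at ZT 19.1 ± 0.5 and 21.6 ± 0.6 h in beta cells. The limma test of the difference called 0 of the 18, 4 adjusted over the list alone and 6 at an unadjusted p under 0.05. The ratio of nuclear RNAs to ribosomal protein mRNAs peaked at ZT 19.1 in alpha and ZT 18.4 in beta cells.

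Of 20 genes of glucose sensing and excitability, 5 were rhythmic in each cell type (6 in alpha and 7 in beta cells adjusted over the list alone, Fisher adjusted p = 0.29 and 0.89). The calcium channel gene Cacna1d peaked at ZT 18.7 ± 0.8 h in alpha and ZT 17.5 ± 1.0 h in beta cells, and the potassium channel gene Kcnma1 at ZT 20.3 ± 0.9 and 19.8 ± 1.0 h. Of 21 exocytosis genes, 2 were rhythmic in alpha cells (2 adjusted over the list alone) and 6 in beta cells (7 adjusted over the list alone, Fisher adjusted p = 1 and 0.56). The vesicle priming genes Unc13a and Unc13b peaked at ZT 19.6 ± 1.0 and 18.2 ± 1.0 h in alpha cells, calls each lost in 12 of 40 other settings. Both were also called in beta cells, where Unc13b peaked at ZT 18.8 ± 0.9 h. In beta cells Syt4, Snap25 and Cplx2 peaked at ZT 18.9 ± 0.7, 17.1 ± 0.8 and 11.4 ± 0.8 h. All 5 glucose sensing genes called in alpha cells and 3 of the 5 in beta cells peaked between ZT16 and ZT22, the window that also held the peak of the nuclear RNA ratio (ZT 19.1 and ZT 18.4).

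Cirbp, a cold-inducible RNA-binding protein gene, peaked at ZT 8.5 ± 0.5 h in alpha and in beta cells (2.42-fold and 2.22-fold), opposite to the heat shock gene Hsph1 at ZT 19.4 ± 0.9 and 19.1 ± 0.8 h. These were the 2 of 11 heat shock and cold-inducible genes called in each cell type (2 and 3 adjusted over the list alone, Fisher adjusted p = 0.99 and 1). Of 9 glucocorticoid and fasting targets, 3 were rhythmic in alpha and 4 in beta cells (3 and 6 adjusted over the list alone, Fisher adjusted p = 0.29 in each). Fkbp5 peaked at ZT 13.2 ± 0.8 h in alpha and ZT 13.4 ± 0.5 h in beta cells. The metallothionein genes Mt2 and Mt1, close paralogs, peaked at ZT 7.0 ± 0.4 and 7.4 ± 0.5 h in alpha cells with 7.44-fold and 5.77-fold ranges. They peaked at ZT 5.9 ± 0.7 and 6.4 ± 0.8 h in beta cells with 2.94-fold and 2.81-fold ranges.

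The hormone genes were not called rhythmic by limma. Gcg in alpha cells had an adjusted p of 0.91, Ins1 and Ins2 in beta cells 0.75 and 0.73, and Sst and Ppy 0.38 and 0.33 in alpha and 0.18 and 0.21 in beta cells. Of 18 beta cell identity genes, Slc30a8 (ZT 6.9 ± 0.6 h), Gjd2 (ZT 8.8 ± 0.9 h) and G6pc2 (ZT 8.1 ± 1.1 h) were rhythmic in beta cells (3 adjusted over the list alone). The call of G6pc2 was lost in 22 of 40 other settings. Nnat, Mafa and Pdx1 were rhythmic in alpha cells (4 adjusted over the list alone). Mafa and Pdx1 had 1.99 ± 1.85 and 2.7 ± 1.24 RPKM in alpha cells and were highest at ZT16, where replicate 1 held an Ins2 level of 1.45% of the mean level in beta cells. That level was 2.09% in replicate 1 of ZT4 and at most 0.696% in the other alpha libraries. Of the alpha cell identity genes only Slc38a5 was rhythmic, in beta cells (1 adjusted over the list alone). It had 1.04 ± 0.377 RPKM there against 29.6 ± 6.97 RPKM in alpha cells, with means of 1.55 RPKM at ZT0 and 1.39 RPKM at ZT4. Replicate 1 of the ZT4 beta cells held a Gcg level of 1.52% of the mean level in alpha cells. Of 14 pan-endocrine genes Insm1 was called in alpha and Foxa2, Insm1 and Isl1 in beta cells (5 and 3 adjusted over the list alone). Of 20 receptors, Ffar1 was called in alpha and Igf1r, Ffar4 and Sstr3 in beta cells (4 and 3 adjusted over the list alone). Of 14 amino acid transporters, Slc7a5 and Slc3a2, which form one transporter, were called in alpha cells and Slc38a5, Slc16a10 and Slc6a6 in beta cells (5 and 4 adjusted over the list alone). The alpha call of Slc3a2 was lost in 25 of 40 other settings and that of Slc7a5 in 14, and the beta calls of Slc6a6 in 16 and Slc16a10 in 10.

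Smaller numbers of calls fell in the remaining lists. Of 47 genes of oxidative phosphorylation, 2 were rhythmic in each cell type, among them Uqcrfs1 in alpha and Cox6c in beta cells (1 in each adjusted over the list alone). Of 40 other settings, the call of Cox6c was lost in 18, and that of Uqcrfs1 was lost in 19 and moved its peak in 1. Of 14 genes of prohormone processing and granules, 0 were rhythmic in alpha cells and Slc30a8 and Ptprn in beta cells (0 and 2 adjusted over the list alone), the call of Ptprn being lost in 12 of 40 other settings. Of 14 cell cycle genes only Mcm2 was rhythmic, in beta cells (0 adjusted over the list alone), a call lost in 20 of 40 other settings. Among markers of other cells, Spp1 of the duct list and Pdgfrb of the stromal list were called in alpha cells, and Bhlha15 of the acinar, Krt7 of the duct and Esam of the endothelial list in beta cells. Of these, Esam lost its call in 12 of 40 other settings and Pdgfrb in 10 of 39. Of the 18 immediate early genes limma called 0 in either cell type (0 adjusted over the list alone, 0 in alpha and 1 in beta cells at an unadjusted p under 0.05). It also called 0 of the delta, PP, immune and glial markers, of which 4, 1, 1 and 2 in alpha cells and 0, 0, 0 and 1 in beta cells had an unadjusted p under 0.05. Adjusted over the list alone, 4 delta and 2 glial markers passed in alpha cells and 0 in beta cells. The Fisher adjusted p of every list of identity genes, receptors, transporters, oxidative phosphorylation, prohormone processing, cell cycle, immediate early genes and markers of other cells lay between 0.97 and 1. The limma test of the difference of rhythm called 0 members of any list.

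The limma test of the difference called 10 genes whose rhythm differed between the cell types, and 8 of them are named by the rule. At an unadjusted p under 0.05 there were 1074 (7.66%), and with log2(RPKM + 1) in place of the deposited values 44 genes were called. Blocks of time point and replicate number, shared by both cell types, gave far more calls, and a replicate term within each cell type gave fewer. These counts are given with the processing below, and the labels do not say whether the numbers pair alpha and beta libraries. Uap1l1 swung 2.15-fold in alpha cells with a peak at ZT 8.6 ± 0.4 h and 1.23-fold in beta cells (limma, adjusted p = 0.0096). Mpp2, a membrane scaffold gene, swung 2.08-fold in beta cells with a peak at ZT 14.5 ± 0.5 h and 1.16-fold in alpha cells (limma, adjusted p = 0.038), and Scnn1b, which encodes a subunit of the epithelial sodium channel, 1.7-fold in beta cells with a peak at ZT 8.4 ± 0.5 h and 1.18-fold in alpha cells (adjusted p = 0.027). Spon2 had a 4.23-fold range in beta and a 2.07-fold range in alpha cells, with a peak difference of -2.7 ± 0.7 h between alpha and beta cells (limma, adjusted p = 0.027). Tnpo2 peaked at ZT 6.6 ± 1.0 h in alpha and ZT 19.5 ± 0.6 h in beta cells (limma, adjusted p = 0.0096), Fam83g at ZT 5.6 ± 1.0 and 20.7 ± 0.7 h, Klhl25 at ZT 4.2 ± 0.9 and 19.5 ± 0.8 h, and Lrrc4 at ZT 23.4 ± 1.1 and 8.1 ± 0.7 h (adjusted p = 0.038 for each of the last 3). The peaks of Lrrc4 rest on few reads, with a mean of 0.186 RPKM in alpha and 0.333 RPKM in beta cells. The calls of Uap1l1 and Tnpo2 held in 37 and 36 of 40 other settings. Those of Scnn1b and Spon2 were lost in 15 and 17 of 40, those of Lrrc4 in 23 of 39, and those of Mpp2, Fam83g and Klhl25 in 25, 26 and 30 of 40. Of the 773 genes called in alpha but not in beta cells, 26.3% had an unadjusted p under 0.05 for the difference, and of the 1659 called in beta but not in alpha cells 23.3%. The count was 4 without replicate 1 of the ZT20 alpha, replicate 2 of the ZT12 alpha, replicate 1 of the ZT12 beta or replicate 2 of the ZT8 beta cells. It was 5 without replicate 1 of the ZT8 or ZT16 alpha cells, replicate 1 of the ZT8 or ZT16 beta cells or replicate 2 of the ZT12 beta cells. It was 6 without replicate 1 of the ZT12 alpha, replicate 2 of the ZT16 or ZT20 alpha or replicate 2 of the ZT16 beta cells.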

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

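The tests of the immediate early genes were chosen only after the result was seen. The genes whose rhythm differed, their count and the later peaks of core clock genes in alpha cells were singled out because a test of the difference between alpha and beta cells itself passed its threshold. The limma test of the difference of rhythm called 10 genes, and for the 8 named ones the adjusted p was 0.0096 for Uap1l1 and Tnpo2, 0.027 for Scnn1b and Spon2, and 0.038 for Lrrc4, Fam83g, Klhl25 and Mpp2. Random assignments of the cell type within time points did not exclude chance for this count: 5 of 100 assignments, the real one included, gave at least 10 genes, and the highest other gave 690, far above the real count, which points to a structure of the libraries whose cause was not tested. The median of the other assignments was 0, and the assignments did not use the replicate numbers. They therefore cannot judge the far larger count from the fit with blocks of time point and replicate number, given with the processing below. The other counts exceeded all other splits drawn, 1 of 100 in each case being the real one. The real 2903 genes between cell types compared with at most 1968, the 1355 rhythmic genes in alpha cells with at most 13 and the 2241 in beta cells with at most 2134. A random assignment of single libraries can be excluded for these 3 counts at the 5% level. The splits behind the 1968 mixed alpha and beta libraries without centring, so an uneven split can carry part of the cell type difference itself. The high value of 2134 also points to a structure of the libraries, whose cause was not tested. Because single libraries were moved, an isolation effect shared by the 2 libraries of a time point is not excluded for the rhythm counts.

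Core clock genes peaked later in alpha than in beta cells, by a median of 1.51 h over 16 genes. A single library as the source is argued against by the lowest median with 1 library left out, 1.29 h without replicate 1 of the ZT8 alpha cells. RNA of the other sorted cell type was tested by leaving out the 3 libraries whose hormone level from the other cell type passed 1%. The median was then 1.59 h (exact permutation, p = 0.00013), so these libraries did not set the difference. Mixing of the 2 RNAs would draw the peak times together, so this test could hardly have come out otherwise. A difference between the cell types in their clocks is a hypothesis that stays open, and so does a share of delta or PP cells in the alpha sort, whose clocks were not measured here.

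Rhythmic genes of both cell types peaked mostly between ZT4 and ZT10 or between ZT16 and ZT22. Gene length is argued against as the whole source, since 88% of the calls were kept after a length trend was removed. With the hormone genes left out of library sizes 97.8% were kept. The deposited library sizes already held a scaling factor between libraries, so this test could change little. It does not decide on the hormone genes' share of the reads. Removing the part of each gene that followed the ratio of nuclear RNAs to 73 ribosomal protein mRNAs kept 65.5% of the calls (63% in alpha, 67% in beta cells), against a median of 94.8% (75.9% to 99.8%) for 20 shuffled ratios. The number of calls rose to 1891 and 3087, the 2 windows held 77.7% and 76.4% of them, and all 16 core clock genes were still called in both cell types, with a median difference of 1.43 h. A nuclear share that differs between isolations may thus account for part of the peaks. It cannot be told apart from a daily rhythm, because the ratio also varied with the time of day and 65.5% lies between the bounds set in advance. Of the variance of the ratio, 34.4% in alpha and 44.2% in beta cells lay between libraries of one time point (54.5% with no effect of time). A rhythm of the ratio itself was not tested.

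Immediate early genes differed between the 2 libraries of one time point, most at ZT8, where the list mean of replicate 1 minus replicate 2 was -2.95 (log2) in alpha and -2.23 in beta cells, and at ZT4, where it was 1.45 and 0.98. The differences in alpha and beta cells correlated over the 6 time points (Pearson r = 0.98, exact permutation p = 0.014, Spearman rho = 0.71, exact permutation p = 0.14, 1 relation computed), and r was 0.47 without ZT8 and ZT4, so the relation rests on these time points. Time of day as the whole source is argued against, since 88.6% of the variance of the list mean within a cell type lay between libraries of one time point (54.5% with no effect of time). A shared effect of the isolation or sort on both cell types is a candidate explanation that fits these values, and a difference between animals stays open, since the labels do not name the animals.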

How the results depend on the processing

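The stricter filter, the nuclear RNA ratio as a covariate and the fits without several libraries were chosen after seeing the data. The count-model test and the second count-model tool were not run, although whole reads were recovered, and limma-voom was run on these reads. A fit with no filter on low values was not run, since the table came already filtered. The phase difference (1.35 to 1.59 h) kept its direction and its side of the threshold under every alternative run, and with 1 library left out it lay between 1.29 and 1.62 h. The number of genes called between cell types was 1602 (690 higher in alpha) with log2(RPKM + 1), 1755 (739 higher in alpha) with the stricter filter, and 10508 (5296 higher in alpha, 5212 in beta) by adjusted p alone, which drops the fold threshold. With 1 library left out it lay between 2872 and 2939 (1546 to 1594 higher in alpha, 1323 to 1350 in beta). Scalings moved the median log2 difference of all genes to at most 0.05.

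Rhythmic genes in alpha and beta cells numbered 531 and 1212 for any difference among time points, 861 and 1037 with 24 h and 12 h cosines, and 143 and 802 with the nuclear RNA ratio as a covariate, after which 13 of the 16 core clock genes were still called in both. A fit on beta libraries alone, with fewer libraries behind the spread, gave 894. In alpha cells the count was 563 without 4 libraries of high cross-hormone reads or low depth, 2449 without replicate 1 of ZT4 in both cell types and 2483 without ZT0. With 1 library left out the counts lay between 348 and 2252 in alpha and between 1077 and 3100 in beta cells. The rhythm of Uqcrfs1 in alpha cells moved its peak by over 6 h with the nuclear ratio as a covariate (limma, adjusted p = 0.99). Genes whose rhythm differed numbered 44 with log2(RPKM + 1), 2 for any difference among time points, 4 with an acinar marker covariate, 2 without the 4 libraries, 6 without ZT0, and 4 to 14 with 1 library left out. Lists called between cell types fell to 1 with an estimated correlation, and lists called among rhythmic genes numbered 7 for any difference among time points and 3 to 5 with 1 library left out. The 5 lists came without replicate 2 of the ZT8 alpha cells, replicate 1 of the ZT8 or ZT16 beta cells or replicate 2 of the ZT20 beta cells. The cause was not tested except where named.

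The replicate numbers were not treated as pairing. Deviations of same-numbered alpha and beta libraries correlated at 0.647, 0.422, 0.338, 0.104, 0.186 and 0.041 from ZT0 to ZT20, so 5 of 6 passed 0.1, and 11 of 12 alpha libraries were closer to the beta library of their number, a hint from the data. With a replicate block the genes called between cell types numbered 2903, the rhythmic genes 1015 and 1777, and the genes whose rhythm differed 4 with the number within the cell type or 174 with 12 blocks. The 4944982 reads in replicate 2 of the ZT12 alpha cells, the lowest depth, limit genes with few reads there.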

Other observations

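The Ppy share of the reads was 1.1% to 2.08% in alpha libraries, against at most 0.0621% in beta libraries, and Sst held 0.15% to 0.322% and 0.0375% to 0.0824%. The mean log2 RPKM of 22 acinar markers, which exocrine cells express, ranged from 1.26 in replicate 1 of ZT0 to 4.31 in replicate 2 of ZT12 in alpha cells and from 1.32 in replicate 2 of ZT8 to 4.25 in replicate 1 of ZT20 in beta cells.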
